A study of Mus musculus with 8 samples.

How the data were processed

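RNA from brown adipose tissue of male C57BL/6 mice was hybridised to 8 Affymetrix Mouse Gene 1.0 ST arrays, a whole-transcript microarray that gives 1 value per transcript cluster, the group of probes placed along a gene. The labels put 4 arrays in a group called NCD and 4 in a group called HFD, which the series title spells out as high-fat diet. The labels do not spell out NCD, and the length of feeding and the age of the mice are not given in the sources used here. Nothing in the labels says that the replicates came from separate animals, so the p-values measure only the spread between these samples.

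Per the series design text, the authors log transformed the intensities and quantile normalized them with Affymetrix Power Tools, which the submitters' processing notes also name, without a version. The deposited values are normalized log2 intensities rounded to the second decimal. The summarization method, background correction, genome build and annotation release are not given in the sources used here. The deposited table held 25254 transcript clusters with a gene symbol, and the values in the other deposited table were identical to it. The authors' table also holds a p-value for diet and a signed fold change for diet per cluster. For the 18447 clusters whose group means differed by more than 0.05, the deposited fold equalled the fold between the group means of log2 values within 0.02 in 100% of cases. The design text names Student's t-test. The deposited p-value lay within 0.01 of a t-test with unequal variances for 75.3% of clusters and within 0.01 of one with equal variances for 55.6%, so which test the authors ran stays open.

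The brightest cluster by mean over all 8 arrays stood for each gene, which left 21759 genes and put aside 3495 clusters of the 1921 genes that had several. Transcript accessions of 19508 genes matched the RefSeq table of assembly GRCm38.p6 and 2251 did not, and the symbol in the file differed from the current symbol for 1924. File symbols were kept. Coordinates below are those of the file, whose build is not named, and no coordinate of the RefSeq table was used, since only 108 start positions were equal. The chromosome of the chosen cluster was compared with that of the RefSeq gene for 100 genes named by rule or past the threshold, and 4 differed.

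Differences are HFD minus NCD on the log2 scale, from limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with a prior of 8.87 degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Errors beside differences are moderated standard errors, and errors beside group means are standard deviations over 4 arrays. There is no count depth on an array: the number of arrays limits the precision, and the median standard error of a difference was 0.127. The 1119 olfactory receptor genes, taken after the data were seen as a stand-in for unexpressed genes, had a median of 4.50 and a 95th percentile of 6.46.

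Before the data were examined, 34 gene lists were fixed for brown and white fat, energy metabolism, immune and stromal cells, muscle, nerve, blood and stress responses. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 34 lists. Camera with a correlation estimated from the data, and fry, which tests whether a list's genes move on balance one way, were run beside it. An exact two-sided permutation test compared each list's array means over the 70 assignments of 4 and 4 arrays, and its smallest possible p is 0.0286. Each list's median was also placed among 10000 random lists matched on mean expression in 20 bins. Random lists hold unrelated genes, so a list whose genes vary together can lie outside them whatever the diet did. No test of annotation terms was run, because the deposited table holds no such column. Lists fixed for cell types describe marker genes in whole tissue and give no cell numbers.

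The genes named were chosen by a rule fixed beforehand. It took the 8 largest rises and falls among genes past the threshold whose groups did not overlap, leaving out predicted genes and receptor families. It took the 4 members with the smallest p of each list past the threshold and 1 of each other list. Ucp1 and Lep were always included. Other genes are named as chosen after their values were seen. Results of some genes are not reported here.

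The steps were tested on simulated data in which 200 of 21759 genes were changed. Each gene had its own residual spread from the fit, the same on all 8 arrays, so arrays of unequal spread were not simulated. The HFD against NCD fit recovered 52.2% of simulated 1.5-fold changes, 94.0% of 2-fold and 100% of 3-fold changes, with 7 false calls and 0 wrong signs. In 50 simulated datasets without any effect, the 34 lists gave 3 false calls in all; these simulations had independent genes.

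Alternatives fixed beforehand were the methods' t-test, other variance models, array weights, the replicate number as a block, a filter on dim genes, median centring, cyclic loess, other handling of several clusters, marker means as covariates, each array left out, other list tests and a minimum fold in the test. The t-test with unequal variances, scalings to equal quantiles or to equal median and spread, the exact list test and the sets of arrays left out together were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.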

Results

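Gene expression was measured in brown adipose tissue, the heat-producing fat depot, of male C57BL/6 mice in 2 groups of 4 arrays each, labelled NCD and HFD (high-fat diet). The series title puts the question as the effect of the high-fat diet on expression in this tissue. Each array gave 25254 normalized log2 values, from which 21759 genes were tested. Array medians lay between 5.91 and 5.99. The standard deviation over clusters ran from 1.69 to 1.82 and was widest on NCD 3 (1.82), NCD 2 (1.79) and HFD 4 (1.78). No pair of arrays was a duplicate: the Pearson correlation of values across clusters, which are not independent, was between 0.976 and 0.991, and at most 2.09% of values were identical.

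Genes that build fatty acids fell in HFD arrays and were 11 of the 31 genes past the threshold. Acly, which makes cytosolic acetyl-CoA from citrate, changed most: its log2 level was 10.68 ± 0.21 (SD, n = 4) in NCD and 8.96 ± 0.15 (SD, n = 4) in HFD, a 3.30-fold fall. Fasn, the fatty acid synthase, fell 2.81-fold, and Elovl6, which lengthens its products, fell 2.54-fold. The 31 genes passed an adjusted p of 0.05 in limma, 29 of them lower and 2 higher in HFD. Each of the 31 differed by at least 1.5-fold, and 15 differed by at least 2-fold, all lower. The HFD arrays lay wholly on one side of the NCD arrays for all 31. The same values gave the calls, so this adds no separate support. Over all genes tested such separation occurred for 3.83%, against 2.86% by chance. At an unadjusted p under 0.05 there were 593 higher and 983 lower genes, 1576 together, where chance alone gives 1088.

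The number of calls varied with the arrays kept and with the variance model. Without NCD 2 and NCD 3, arrays of wide spread, 3 genes passed: Acly and Elovl6 of the 31, and Lep, the leptin gene. Without those arrays and HFD 4, 1 gene passed (Acly). Without NCD 1 and HFD 3, which leaves as many arrays, more evenly split between the diets, 37 genes passed. Fewer arrays leave less power, and these fits also differ in the split between the diets and in which arrays were removed. The cause of the fall to 3 was thus not settled. Without NCD 2 and NCD 3 all 31 genes kept their sign, while 26 of the differences shrank. The median ratio to the difference over all arrays was 0.858 (range 0.709 to 1.16). Fasn stood at -1.395 (adjusted p = 0.0675) and Elovl3 at -1.0475 (adjusted p = 0.149). Among the lost calls, Rnd3 lay nearest the threshold (limma adjusted p = 0.0526) and Fabp5 furthest from it (0.373). Me1, Acaca, Tkt, Pygl, Acss2 and Prune2 each had a limma adjusted p of 0.0531. Genes called lower numbered 19 without HFD 1, and genes called higher numbered 5 without NCD 3, 5 without HFD 2 and 1 without HFD 4. After cyclic loess the calls split into 8 higher and 29 lower. The methods' t-test called 0 genes after adjustment and 1514 at an unadjusted p under 0.05, and limma with a variance trend and robust prior called 70. In the authors' deposited table, 1633 clusters had a p of at most 0.05, and 106 of these also had a fold of at least 1.5, 80 lower and 26 higher.

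Of the 22 measured members of the fatty acid synthesis list, 11 fell, 0 rose and 11 did not pass; 18 fell when adjusted over the list alone. All 22 means were lower in HFD, and 18 members were separated between the groups. The median log2 difference was -0.70, against -0.12 to 0.02 for the central 95% of random lists of like expression. The mean over the list was 9.57 ± 0.16 (SD, n = 4) in NCD and 8.76 ± 0.12 (SD, n = 4) in HFD, with no overlap between arrays. Camera gave an adjusted p of 6.35e-45, fry an adjusted p of 0.00653, and camera an adjusted p = 0.0852 with an estimated correlation.

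The members that fell cover the supply of carbon and of NADPH as well as chain building. Acly had a log2 difference of -1.72 ± 0.13 (SE, adjusted p = 2.02e-05) and Slc25a1, the mitochondrial citrate carrier, one of -1.23 ± 0.15 (SE, adjusted p = 0.00209). Acss2, which makes acetyl-CoA from acetate, fell by 1.19 on the log2 scale. Acaca, which makes malonyl-CoA, fell by 1.08 and Fasn by 1.49. The Acaca call was lost with equal median and spread. Among NADPH-producing steps, Me1, the cytosolic malic enzyme, fell by 1.30 and Pgd of the pentose phosphate pathway by 0.81. G6pdx, a list member of that pathway, did not pass. Tkt, a transketolase of the same pathway, fell by 1.16. The elongase Elovl6 had a difference of -1.345 and the desaturase Scd2 one of -1.305, while the related desaturase Scd1 stood at 13.16 in NCD and 13.01 in HFD (difference -0.15, adjusted p = 0.823), near the 13.79 that was the highest value on any array. The Scd2 mean in HFD, 6.295, lies under the 95th percentile of olfactory receptors (6.46), so the size of its fall is uncertain. Thrsp, a lipogenic regulator, fell by 0.68, and its call was lost in 6 of the 8 runs that left out an array, those without NCD 2, NCD 4 or any of the HFD arrays (largest adjusted p 0.120). It was also lost after cyclic loess, with equal quantiles, with equal median and spread, and without NCD 1 and HFD 3 together. The Pgd call was lost without NCD 2, NCD 3, HFD 1, HFD 2 or HFD 3 (largest adjusted p 0.138), and with median centring. The transcription factors Mlxipl and Srebf1, which act on lipogenic genes, had differences of -0.58 (adjusted p = 0.0935) and -0.14 (adjusted p = 0.844). Tkt, Acss2, Thrsp, Pgd, G6pdx, Scd1, Mlxipl and Srebf1 were chosen after their values were seen.

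**Figure D1:**
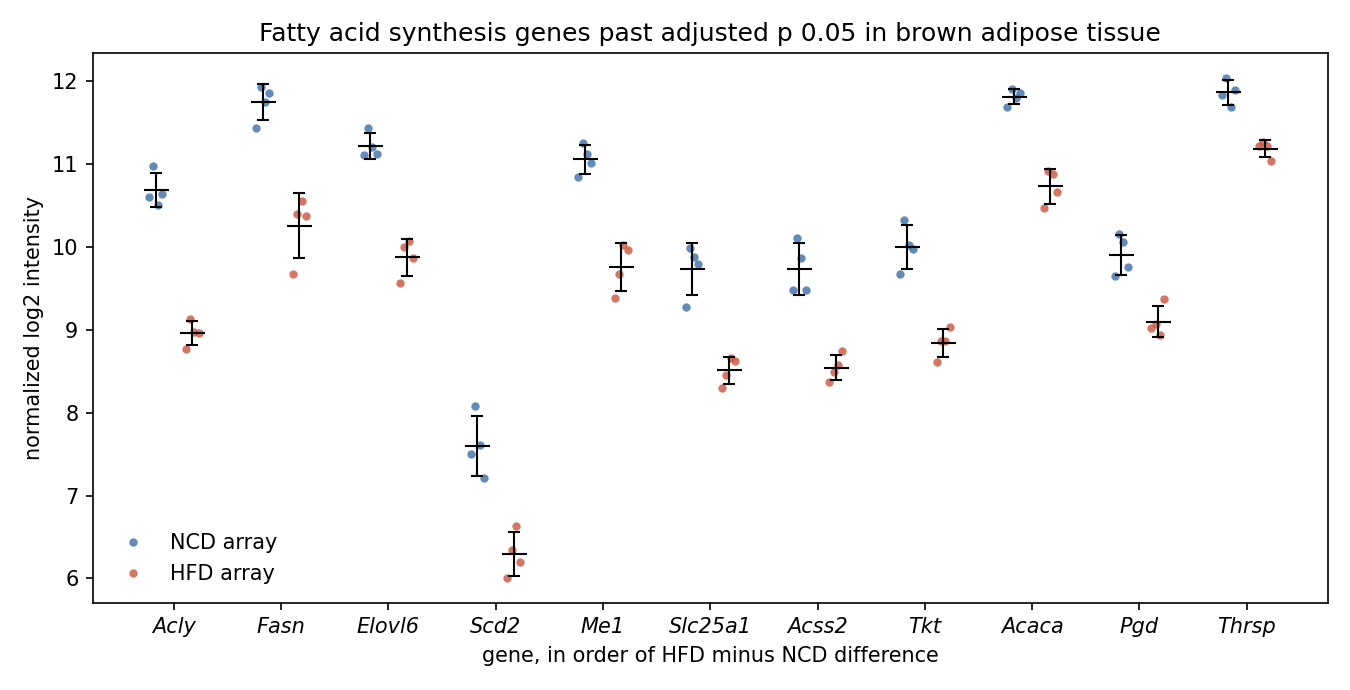
Normalized log2 intensity (vertical axis) of the 11 fatty acid synthesis genes past the threshold, ordered by difference; each point is an array (4 NCD in blue, 4 HFD in red) and black bars give the mean and SD. The HFD points lie below the NCD points for every gene shown, from Acly (difference -1.72) to Thrsp (-0.68).

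In the file, whose build is not given in the sources used here, the Acly cluster spans chromosome 11 from 100337670 to 100389215, Fasn chromosome 11 from 120667272 to 120685861, Elovl6 chromosome 3 from 129235304 to 129341413 and Me1 chromosome 9 from 86474983 to 86589834. These spans cover whole genes, and exon positions were not used here. The brightest Acaca cluster is annotated to chromosome 12, from 10158946 to 10165038, while the RefSeq gene lies on chromosome 11. A second Acaca cluster, on chromosome 11, differed by -1.46 ± 0.14 (SE, adjusted p = 0.00145 over all clusters).

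The cholesterol synthesis list was also lower in HFD, with 0 of 24 members past the threshold over all genes and 11 lower when adjusted over the list alone. Its median difference was -0.34 (camera adjusted p = 3.84e-12, adjusted p = 0.0852 with an estimated correlation, fry adjusted p = 0.0302), and 21 members had lower means. Nsdhl, a demethylation enzyme of the pathway, differed by -0.73 ± 0.14 (SE, adjusted p = 0.0552). Idi1, the isopentenyl diphosphate isomerase, differed by -0.82 (adjusted p = 0.0753), with an HFD mean of 6.01 under the 6.46 of olfactory receptors, on a cluster annotated to chromosome 2, and by -0.89 on a cluster on chromosome 13, where the RefSeq gene lies. Insig1, a sterol-responsive regulator of the pathway, differed by -0.81 (adjusted p = 0.0817).

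Genes of glucose uptake and glycolysis had a median difference of -0.24, with lower means for 19 of 21 members (camera adjusted p = 4.57e-09, adjusted p = 0.326 with an estimated correlation). Eno1, an enolase, fell by 0.77 (adjusted p = 0.0162), 0 members rose, and 7 fell when adjusted over the list alone. The Eno1 call was lost in 5 of the 8 runs that left out an array, those without NCD 2, NCD 3, HFD 1, HFD 2 or HFD 4 (largest adjusted p 0.0959). It was also lost with the mean of its clusters (-0.648, adjusted p = 0.0533) and with equal median and spread. The chosen Eno1 cluster is annotated to chromosome 2, whereas a cluster on chromosome 4, that of the RefSeq gene, differed by -0.49 ± 0.12 (SE, adjusted p = 0.232 over all clusters). Slc16a1, a lactate and pyruvate transporter, differed by -0.47 (adjusted p = 0.166), the hexokinase Hk2 by -0.51 (adjusted p = 0.265) and Pkm2, the muscle-type pyruvate kinase (current symbol Pkm), by -0.45 (adjusted p = 0.286).

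Subunits of oxidative phosphorylation were lower by a small amount: 71 of 76 had lower means, 0 passed the threshold in either direction over all genes or over the list alone, and the median difference was -0.17 (camera adjusted p = 3.84e-12, adjusted p = 0.569 with an estimated correlation). Sdhd of complex II differed by -0.47 (adjusted p = 0.320) and Ndufa2 of complex I by -0.46 (adjusted p = 0.414). The list mean was highest on NCD 2 (10.55) and NCD 3 (10.57), the NCD arrays of widest spread, and the array means of the groups overlapped. Without those arrays the median was -0.07 (camera adjusted p = 0.103), and with every array set to equal median and spread it was -0.05 (camera adjusted p = 0.0421).

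The brown adipocyte and thermogenic list had a median of -0.105 (camera adjusted p = 0.00689, adjusted p = 0.569 with an estimated correlation), with 2 of 32 members lower, 0 higher and 30 not past; 3 fell when adjusted over the list alone. The members that fell were Elovl3, a fatty acid elongase, by 1.39 to an HFD mean of 5.82 (adjusted p = 0.00673), and Mpzl2, a cell adhesion protein, by 0.79 (adjusted p = 0.0148). As the Elovl3 mean in HFD lies under the 6.46 of the 95th percentile of olfactory receptors, the size of its fall is uncertain. The Mpzl2 call was lost without NCD 2, HFD 1 or HFD 4 (largest adjusted p 0.0788). Acot11, a thioesterase, differed by -0.60 (adjusted p = 0.0698) and Kng2, a kininogen, by 0.43 (adjusted p = 0.507). Ucp1, the uncoupling protein of brown fat, had a log2 level of 12.90 ± 0.05 (SD, n = 4) in NCD and 12.85 ± 0.05 (SD, n = 4) in HFD, a difference of -0.05 with a 95% interval from -0.27 to 0.17 (adjusted p = 0.945), again close to the top of the array's range. The list lost its call without NCD 3 (median -0.05, adjusted p = 0.161), with equal median and spread (median -0.063, adjusted p = 0.171), without NCD 2 and NCD 3 (median -0.0275, adjusted p = 0.463) and without those and HFD 4 (adjusted p = 0.224).

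Other metabolic lists passed less firmly. Triglyceride storage and lipolysis had a median of -0.10 (camera adjusted p = 0.00205, adjusted p = 0.6002 with an estimated correlation), and 1 of its 28 members fell, 4 over the list alone: Fabp5, a fatty acid binding protein, by 0.87 (adjusted p = 0.0399). Fabp5 was past the threshold in 3 of the 8 runs that left out an array. The lipid droplet protein Plin2 differed by -0.43 (adjusted p = 0.277) and Agpat2, an acyltransferase of triglyceride assembly, by -0.56 (adjusted p = 0.134). The list was not past the threshold without NCD 3 (median -0.0475, adjusted p = 0.161), without HFD 1 (median -0.073, adjusted p = 0.0651), with equal median and spread (median -0.017, adjusted p = 0.353), without NCD 2 and NCD 3 (median -0.00125, adjusted p = 0.846) or without those and HFD 4 (adjusted p = 0.242). The tricarboxylic acid cycle list had a median of -0.08 (camera adjusted p = 0.0137, adjusted p = 0.660 with an estimated correlation) and 0 of 19 members past, led by Pdhb of pyruvate dehydrogenase at -0.59 (adjusted p = 0.0948). Its median turned to 0.06 with arrays set to equal median and spread and to 0.03 without NCD 2 and NCD 3, and its call was lost without NCD 2, NCD 3 or HFD 1 (adjusted p = 0.0901, 0.175 and 0.0855). The call was also lost after cyclic loess (median -0.024, adjusted p = 0.142) and with equal quantiles (median -0.0095, adjusted p = 0.306). The antioxidant list had a median of -0.12 (camera adjusted p = 0.0137, adjusted p = 0.660 with an estimated correlation) with 0 of 28 members past, led by Gpx4, a lipid peroxidase, at -0.46 (adjusted p = 0.277). It turned to 0.005 without NCD 2 and NCD 3 and lost its call after cyclic loess (median -0.059, adjusted p = 0.141), with equal quantiles (adjusted p = 0.130) and with equal median and spread (median -0.031, adjusted p = 0.494). It also lost its call without NCD 2, NCD 3, HFD 1 or HFD 2 (adjusted p = 0.239, 0.161, 0.169 and 0.114).

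Among lists that did not pass, fatty acid oxidation had a median of -0.03 (adjusted p = 0.430) with 1 of 37 members lower, Acsl5, an acyl-CoA synthetase that also serves lipid synthesis, by 1.17 (adjusted p = 0.00369). The hypoxia list (median -0.08, adjusted p = 0.0661) held Pdk1, a kinase that inhibits pyruvate dehydrogenase, which fell by 0.96 (adjusted p = 0.0124) and lost its call without NCD 2, HFD 1, HFD 2 or HFD 4 (largest adjusted p 0.0733); without HFD 3 the list itself passed (adjusted p = 0.0496). The median was -0.03 for insulin signalling (adjusted p = 0.425), -0.07 for adrenergic signalling (adjusted p = 0.125), -0.10 for branched-chain amino acid breakdown (adjusted p = 0.0617), -0.08 for endoplasmic reticulum stress (adjusted p = 0.129) and 0.01 for cell cycle (adjusted p = 0.120). Single arrays mattered here too: branched-chain amino acid breakdown passed as lower without NCD 1, NCD 4 or HFD 4 (adjusted p = 0.00771, 0.00797 and 0.00107), endoplasmic reticulum stress as lower without NCD 1 or NCD 4 (adjusted p = 0.0385 and 0.0416), and cell cycle as higher without NCD 3 (adjusted p = 0.0139). The lysosome list had a median of -0.02 (adjusted p = 0.302) and passed as lower without NCD 1 (adjusted p = 0.0385) or HFD 4 (adjusted p = 0.0319), but as higher without NCD 2 and NCD 3 together (median 0.12, adjusted p = 0.0225).

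Lists of stromal and vascular cells were slightly higher in HFD arrays, with 0 members past the threshold in any of them. Progenitor and fibroblast markers had a median of 0.14 and higher means for 17 of 20 members (camera adjusted p = 0.000248, adjusted p = 0.397 with an estimated correlation); Fmo2, a monooxygenase, differed by 0.43 (adjusted p = 0.421). Extracellular matrix genes had a median of 0.06 (camera adjusted p = 0.0118, adjusted p = 0.569 with an estimated correlation), with Col12a1, a collagen, at 0.76 ± 0.15 (SE, adjusted p = 0.0698) and the only member past when adjusted over the list alone. Endothelial markers had a median of 0.09 and mural cell markers one of 0.10 (camera adjusted p = 0.0137 and 0.0395, each with an adjusted p = 0.569 with an estimated correlation). In these lists Flt1, an endothelial growth factor receptor, differed by 0.27 (adjusted p = 0.684) and Rgs5, a pericyte gene, by 0.35 (adjusted p = 0.429). Without NCD 1 and HFD 3, the arrays with high muscle markers, none of these 4 lists passed (adjusted p = 0.0773, 0.130, 0.177 and 0.167), though their medians with 6 arrays stayed of like size (0.108, 0.055, 0.097 and 0.14), so the lost calls do not show that those arrays were the source. Without NCD 2 and NCD 3 progenitor and endothelial medians were larger (0.259 and 0.155, adjusted p = 4.58e-06 and 0.000125), the matrix list passed (0.049, adjusted p = 0.0489) and the mural list did not (0.0525, adjusted p = 0.186). Single arrays also ended calls: NCD 2 and HFD 3 for the matrix list (adjusted p = 0.345 and 0.168), NCD 1, NCD 4 and HFD 4 for endothelial markers (adjusted p = 0.0860, 0.134 and 0.140), and NCD 2, NCD 4, HFD 3 and HFD 4 for mural markers (adjusted p = 0.262, 0.0756, 0.199 and 0.121).

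Most immune lists did not pass. The mean level was 5.11 for T and NK cell, 5.45 for B cell and 5.09 for mast cell, neutrophil and eosinophil markers. It was 5.79 for cytokines and chemokines, 6.06 for the interferon list and 6.19 for macrophage markers. These lie under the 6.46 of olfactory receptors, so members may be unexpressed and a missing call is weak evidence of no change. Antigen presentation (7.10) and lipid-laden macrophage genes (7.08) lay above it. The type I interferon list had a median of 0.10 and 18 of 28 members with higher means, with 0 past (camera adjusted p = 0.00553, adjusted p = 0.445 with an estimated correlation). Its smallest p was that of Isg15, at 0.35 (adjusted p = 0.540), which lay under the 95th percentile of olfactory receptors (6.46) in both groups and whose cluster is annotated to chromosome 17 although the RefSeq gene lies on chromosome 4. The interferon list was not past without NCD 1 (median 0.032, adjusted p = 0.0759) or without NCD 1 and HFD 3 (median 0.095, adjusted p = 0.167), and its median rose to 0.261 without NCD 2 and NCD 3 (adjusted p = 5.15e-06). Macrophage markers had a median of 0.06 (adjusted p = 0.115), with Cd68, a macrophage surface and lysosome protein, at 0.37 (adjusted p = 0.547); they passed without NCD 3 (adjusted p = 0.000492), without HFD 2 (adjusted p = 0.00115) and without NCD 2 and NCD 3 (median 0.129, adjusted p = 0.000175). Lipid-laden macrophage genes had a median of 0.02 (adjusted p = 0.638; 0.0439 without NCD 3), with Fabp5 as the member that fell, cytokines and chemokines 0.05 (adjusted p = 0.0690; 0.0231 without HFD 2), antigen presentation -0.10 (adjusted p = 0.250; median -0.193 and adjusted p = 0.0317 without NCD 1 and HFD 3) and mast cell, neutrophil and eosinophil markers 0.04 (adjusted p = 0.106; 0.0416 without NCD 1). For T and NK cell markers (median -0.06, mean -0.01, test direction up, adjusted p = 0.852) and B cell markers (median -0.02, mean 0.03, test direction up, adjusted p = 0.462) the signs of median, mean and test differed. Schwann cell and nerve markers (median 0.02, adjusted p = 0.430) and blood markers (median -0.04, adjusted p = 0.669) did not pass.

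Circadian clock genes had a median of 0.13 (camera adjusted p = 0.0302, adjusted p = 0.6002 with an estimated correlation), and when adjusted over the list alone 6 of 19 were higher and 2 lower. Nfil3, a repressor in the clock network, differed by -0.85 ± 0.17 (SE, adjusted p = 0.0817 over all genes), and Bhlhe41, another repressor, by 0.77 ± 0.19 (SE, adjusted p = 0.220). Nr1d2, a nuclear receptor of the clock, differed by 0.46 (adjusted p = 0.371) and Per3 by 0.51 (adjusted p = 0.473). The NCD means of Bhlhe41 (6.11) and Per3 (6.095) lie under the 6.46 of olfactory receptors, so the size of those differences is uncertain. The time of day of sampling is not given in the sources used here. The call was lost without NCD 1, NCD 4 or HFD 4 (median 0.095, 0.0875 and 0.0075, adjusted p = 0.0858, 0.222 and 0.375), with the smallest median without HFD 4. It was also lost without NCD 1 and HFD 3 (median 0.14, adjusted p = 0.0929), and without NCD 2 and NCD 3 the median rose to 0.2325 (adjusted p = 0.000175). White adipocyte genes had a median of 0.11 (adjusted p = 0.0617; 0.0385 without NCD 1 and 0.0409 without NCD 2). Lep, which encodes the adipocyte hormone leptin, was 8.72 ± 0.72 (SD, n = 4) in NCD and 9.62 ± 0.07 (SD, n = 4) in HFD. The difference was 0.90 ± 0.25 (SE, adjusted p = 0.308), and all HFD arrays lay above all NCD arrays. Lep passed without NCD 2 and NCD 3 (difference 1.47, adjusted p = 0.0256). Those are the NCD arrays with the highest Lep (9.34 and 9.25, against 8.52 and 7.79), so leaving them out itself raises the difference.

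Skeletal muscle markers separated single arrays, not the diets. Their mean was 8.28 on NCD 1 and 9.08 on HFD 3, against 5.61 to 5.90 on the other NCD arrays and 5.67 to 5.82 on the other HFD arrays. Between the diets the median was 0.24 (adjusted p = 0.0579), and it moved to 0.92 without NCD 1 and to -0.59 without HFD 3, past the threshold each time (adjusted p = 8.81e-09 and 6.37e-06). It also passed as higher without HFD 1, HFD 2 or HFD 4 (median 0.51, 0.49 and 0.53). With all arrays, camera called it higher with a variance trend and robust prior (adjusted p = 0.0489), the replicate block (0.0306) or median centring (0.0337). The lymphocyte covariate (0.0433) and camera on ranks (0.0181) gave a call too. Array weights (0.184), the dim-gene filter (0.0545), the mean of a gene's clusters (0.0510), cyclic loess (0.242), equal quantiles (0.310) and equal median and spread (0.127) gave none. The calcium and creatine cycling list, which shares Atp2a1 and Ryr1 with the muscle list, was also high on NCD 1 (7.19) and HFD 3 (7.45). Its median was 0.07 (camera adjusted p = 0.0448, adjusted p = 0.413 with an estimated correlation), it had 0 of 14 members past, and Ryr2, a calcium release channel, differed by 0.74 (adjusted p = 0.0856), a size left uncertain by an NCD mean of 5.98, under the 6.46 of olfactory receptors. The list was not past without NCD 1 and HFD 3 (adjusted p = 0.125), without NCD 2, NCD 3 or NCD 4 (adjusted p = 0.0998, 0.0680 and 0.183), or without HFD 3 (median -0.01, adjusted p = 0.5997). Its call was also lost with the muscle covariate, array weights, the dim-gene filter and the mean of a gene's clusters.

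**Figure D2:**
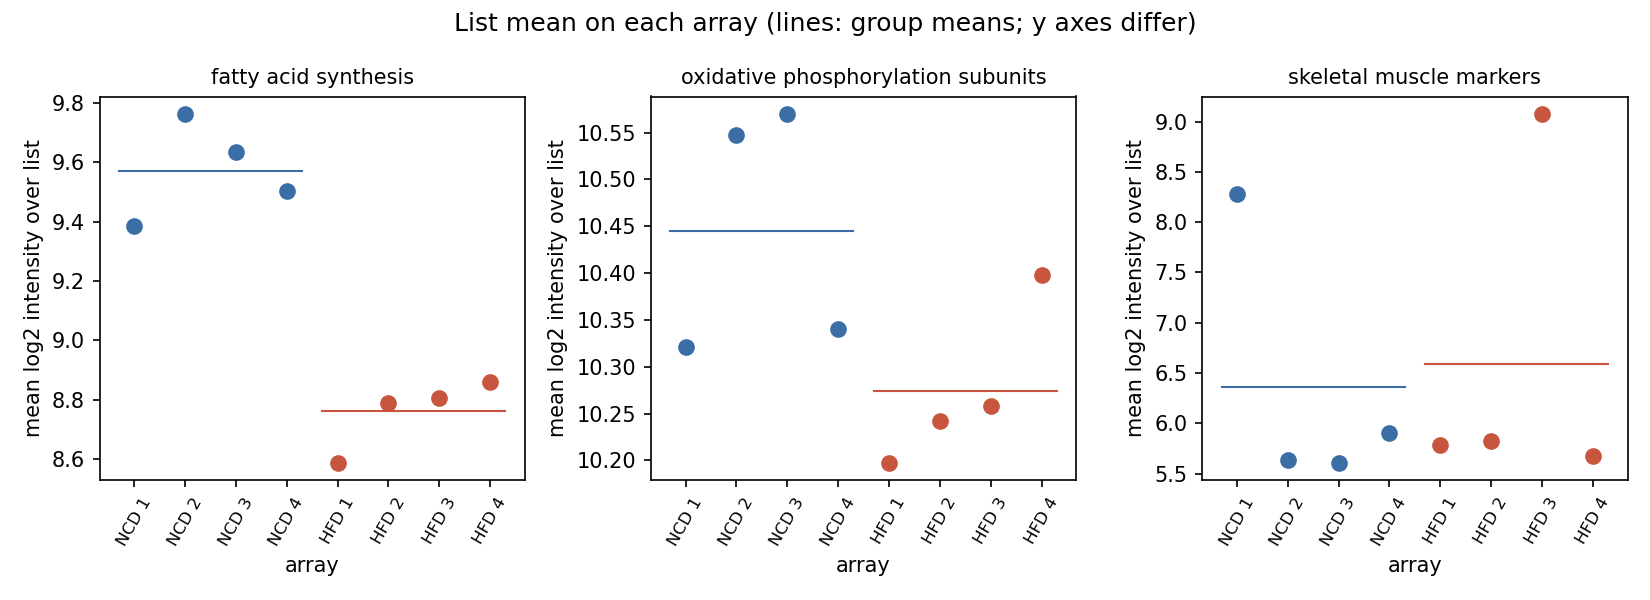
Mean normalized log2 intensity over the members of 3 lists (vertical axes, which differ in range) on each of the 8 arrays (NCD blue, HFD red; lines are group means). Fatty acid synthesis means do not overlap between the diets, oxidative phosphorylation is highest on NCD 2 (10.55) and NCD 3 (10.57), and muscle markers are high on NCD 1 (8.28) and HFD 3 (9.08).

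In sum 15 of the 34 lists passed in camera, 8 lower and 7 higher in HFD. Of the 15 medians, 12 lay outside the central 95% of random lists of like expression. Lists that did not pass lay outside too, such as skeletal muscle (percentile 100), white adipocyte (99.85) and macrophage markers (98.86). That count of 12 is thus no separate support for the calls. Other splits of the arrays also reached 15 lists (7 of 35 splits gave as many, the diet split included). Some were balanced between the diets, such as NCD 1, NCD 2, HFD 1 and HFD 2 against the rest (18 lists). Others followed the diet in part, such as NCD 1, HFD 1, HFD 3 and HFD 4 against the rest (20 lists). With an estimated correlation 0 lists passed, with 3 at an unadjusted p under 0.05. Fry called 2, fatty acid and cholesterol synthesis. The exact permutation test called 0 after adjustment, with 4 lists at its smallest p of 0.0286, which became 0.243 when adjusted. It could pass lists only if many shared that smallest p, so this 0 says little.

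**Figure D3:**
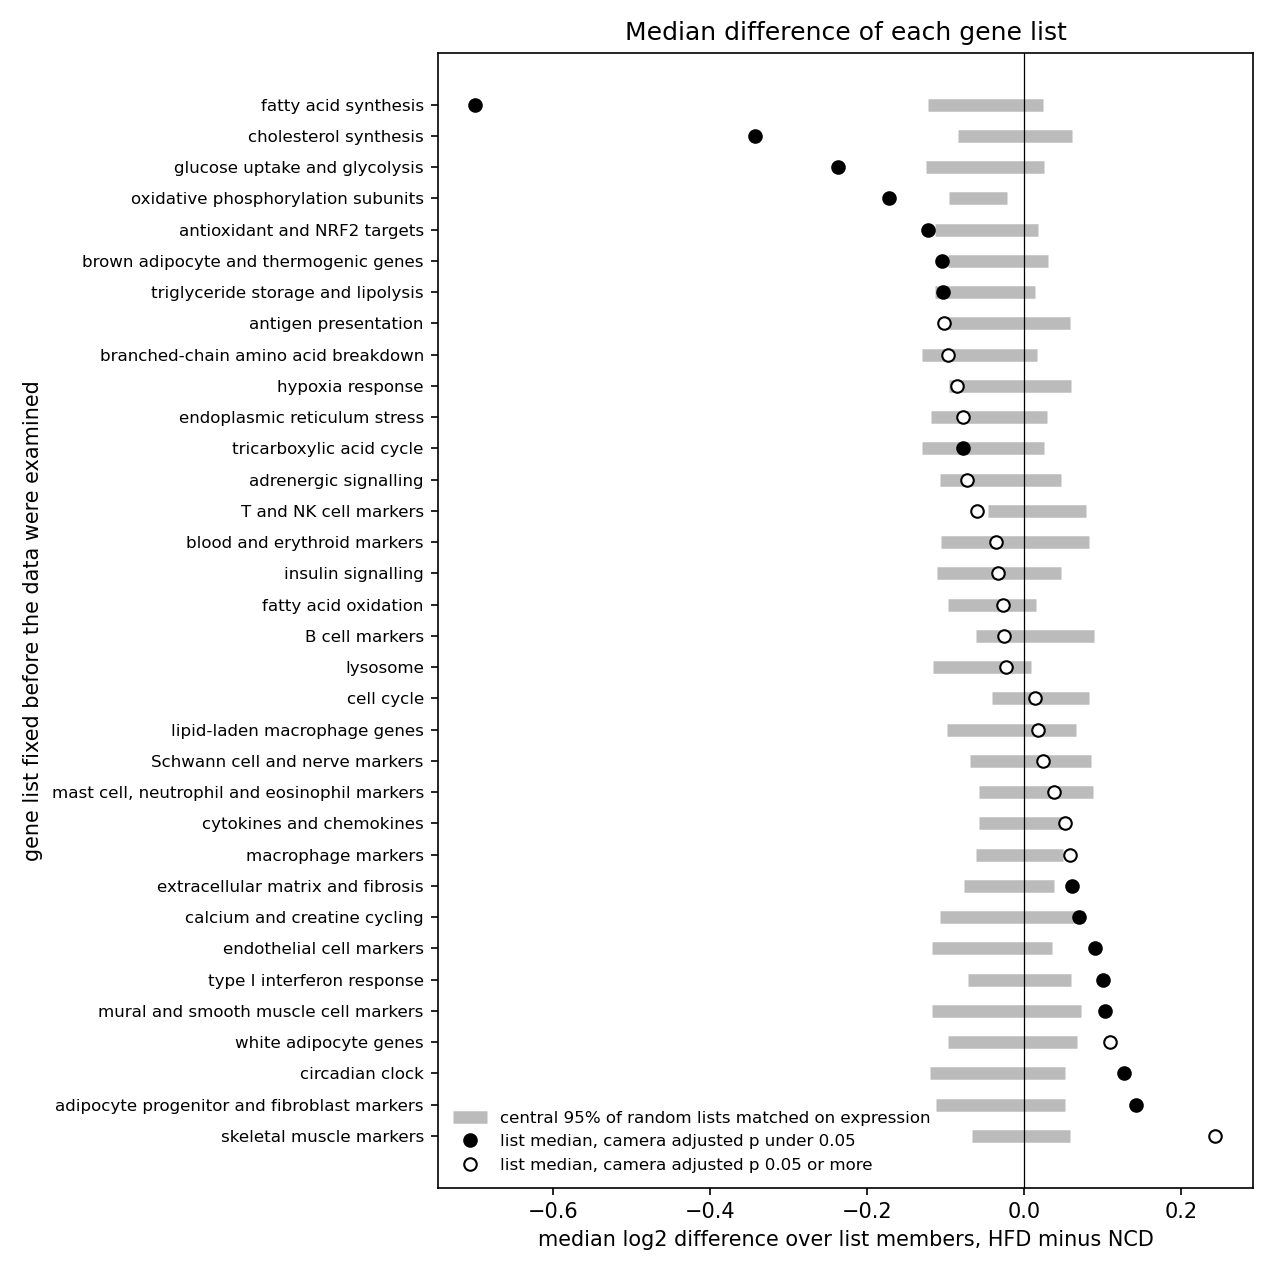
Median log2 difference, HFD minus NCD (horizontal axis), of each of the 34 lists; filled points passed camera at an adjusted p of 0.05, open points did not, and grey bars give the central 95% of random lists matched on expression. Fatty acid synthesis lies lowest at -0.70, and skeletal muscle markers, which did not pass, lie highest at 0.24.

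Genes past the threshold outside every list numbered 14. Slc2a5, a fructose transporter, fell 2.52-fold, from 6.45 ± 0.60 (SD, n = 4) to 5.12 ± 0.10 (SD, n = 4). Both means lie under the 6.46 of the 95th percentile of olfactory receptors, so the size of this fall is uncertain, and its call (adjusted p = 0.0162) was lost with a variance trend and robust prior, after cyclic loess or equal quantiles, and without NCD 4, HFD 1 or HFD 4 (largest adjusted p 0.0810). The rises were Rnd3, a small GTPase that acts on the actin skeleton, by 0.79 ± 0.11 (SE, adjusted p = 0.00737), and Epdr1, a secreted protein, by 0.75 ± 0.14 (SE, adjusted p = 0.0489). The Epdr1 means, 5.18 and 5.93, also lie under 6.46, which leaves the size of that rise uncertain. The Epdr1 call was lost with median centring, after cyclic loess, with the mean of a gene's clusters, with equal quantiles and with equal median and spread. Epdr1 was past the threshold in 1 of the 8 runs that left out an array, the one without NCD 1. Of the 31 genes, 19 passed in all 8 such runs.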

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

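The tests of the muscle pattern, of the arrays NCD 2 and NCD 3 and of the separated fatty acid members were chosen after the results were seen. Of 240 groups of 4 arrays examined for a value far from the rest, 15 stood out, close to the share of about 5% that chance gives. Single genes among them may thus stand out by chance.

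Genes of fatty acid synthesis were lower in HFD arrays. When the 8 arrays were split into 4 and 4 in all 35 ways, only the diet split gave as many genes past the threshold (1 of 35). It gave 31 genes, against a highest count of 0 among the others. A random split would rank first in 1 of 35 cases, so chance is argued against for the count of genes but not excluded. Unequal spread of values between arrays is argued against: the list's median was -0.63 after cyclic loess and -0.64 with equal median and spread, below the -0.35 set as the bound by more than the 0.045 spread of medians with an array left out. Muscle in NCD 1 and HFD 3 is argued against too, since the median without them was -0.74. That 18 of 22 members were separated restates the pattern. The diet cannot be told apart from anything else that differed between the groups, such as time of day, food intake before sampling or handling, since the labels record none of these.

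Oxidative phosphorylation subunits were lower by a small amount, and technical explanations stay open. Without NCD 2 and NCD 3 the median was -0.065. Those were the NCD arrays with the highest list mean (10.55 and 10.57, against 10.32 and 10.34). Leaving them out thus itself shrinks the difference, and cannot tell whether they were its source. Unequal spread cannot be told apart from the diet here: the median was -0.11 after cyclic loess, which met the bound of -0.10 written beforehand by less than the 0.032 spread of medians with an array left out, and -0.05 with equal median and spread. By the bound alone unequal spread would have been argued against; the added margin and the equal-spread condition were set after the value was seen. For the number of lists past the threshold chance is not excluded: 7 of the 35 splits, the diet split included, gave at least its 15 lists, and the highest other split gave 20. That highest split followed the diet in part, and splits balanced between the diets gave up to 18.

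Skeletal muscle markers were far above the rest of their group on NCD 1 (8.28) and HFD 3 (9.08), and 31 of the 32 markers lay above the other 6 arrays on both. That pattern is consistent with muscle taken along with the fat, as a hypothesis. A response of muscle genes to the diet as the source of these 2 high arrays is argued against, because NCD 1 was high without the high-fat diet and only 1 HFD array had a mean above every NCD array. A smaller response beside it stays open. The calcium and creatine cycling list, which shares genes with the muscle list, stood apart on the same arrays, at 7.19 on NCD 1 and 7.45 on HFD 3.

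Other single values lay far from their group. The lipid-laden macrophage list had a mean of 7.33 on NCD 3 against 6.96 to 7.00 on the other NCD arrays. Acot11 was 6.85 on NCD 4 against 7.18 to 7.22, and 6.64 on HFD 4 against 6.46 to 6.47. Nr4a2 was 7.58 on NCD 4 against 7.25 to 7.30, and 6.83 on HFD 1 against 7.04 to 7.08. On NCD 1, Rgs5 was 10.71 against 10.99 to 11.03, F3 was 6.67 against 7.15 to 7.23, Pdha1 was 11.08 against 11.41 to 11.42, and Tnni1, a muscle gene, was 5.93 against 5.12 to 5.20. Lep was 9.52 on HFD 1 against 9.65 to 9.67, and Xaf1 was 7.14 on HFD 3 against 6.96 to 6.98.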

How the results depend on the processing

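The t-test with unequal variances and the scalings to equal quantiles or to equal median and spread were chosen after seeing the data. So were the exact list test and the sets of arrays left out together. The cause of a changed count was not tested. Against 31 genes (2 higher, 29 lower, 31 with at least 1.5-fold) in limma, the methods' t-test gave 0 in every count after adjustment and 1514 (573 higher, 941 lower, 97 with the fold) at an unadjusted p under 0.05. With unequal variances it gave 0 and 1268 (474 higher, 794 lower, 92 with the fold). A variance trend with a robust prior gave 70 (10 higher, 60 lower, 58 with the fold). The lymphocyte marker covariate gave 50, 9 of them higher. Genes called higher numbered 1 with median centring, 1 with the mean of a gene's clusters, 1 over all clusters, 4 with equal quantiles, 5 with the muscle covariate and 8 after cyclic loess. Treat against 1.2-fold called 12. With fewer arrays, omitting NCD 2 and NCD 3 left 3 genes (1 higher, 2 lower, 3 with the fold), and omitting those and HFD 4 left 1 (0 higher, 1 lower, 1 with the fold). Omitting NCD 1 and HFD 3 gave 37 (2 higher, 35 lower, 37 with the fold). Leaving out 1 array at a time gave 21 to 38 genes, 1 to 5 higher and 19 to 36 lower, 21 to 38 with the fold, and 11 to 18 lists.

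Of the 15 lists past the threshold, 0 passed with an estimated correlation and 2 with fry. In the exact permutation test 0 passed. Its smallest possible p of 0.0286 can pass after adjustment only if many lists share it, so that 0 says little. All 22 gene-level alternatives kept fatty acid synthesis (median -0.78 to -0.57), cholesterol synthesis (-0.36 to -0.21) and glycolysis (-0.31 to -0.17) past the camera threshold. Where a list passed in at least 1 of the compared fits, those whose direction turned were skeletal muscle without HFD 3 (-0.59, against 0.92 without NCD 1), the tricarboxylic acid cycle with equal median and spread (0.063) and without NCD 2 and NCD 3 (0.03), and, without those arrays, antioxidant genes (0.005) and the lysosome (0.12). Others changed direction without a call, 11 of them without NCD 2 and NCD 3, among them skeletal muscle (-0.396), and medians near 0 crossed it without NCD 2 for extracellular matrix (-0.0004) and without HFD 3 for calcium and creatine cycling (-0.006).

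The values showed no pairing by replicate number, though they cannot exclude one. Deviations of same-numbered arrays correlated by 0.00, -0.03, -0.03 and -0.17 across genes, and 0 of 4 NCD arrays were closest to their own number. With the number as a block, 36 genes passed, 4 of them higher and 30 shared with the 31, and 18 lists. No depth applies to arrays. Genes under the 6.46 of olfactory receptors may be unexpressed. Restricting to the upper 60% by mean gave 36 genes, but with array medians of 5.91 to 5.99 this filter keeps many genes under 6.46.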

Other observations

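The genes and lists described here were chosen after the main results were seen; the tests of the glycogen and carbohydrate-response lists were fixed before those lists were examined. Of the 14 genes past the threshold outside every list, which were not tested for a shared function, Pygl, the liver-type glycogen phosphorylase, fell 2.05-fold, from 11.03 ± 0.22 (SD, n = 4) to 9.99 ± 0.12 (SD, n = 4) with limma's adjusted p = 0.00209. Lctl, a glycosidase-like membrane protein, fell 2.27-fold (adjusted p = 0.00743), and B3galt2, a galactosyltransferase, 2.11-fold (adjusted p = 0.0148). Chn1, a GTPase-activating protein for Rac, fell 1.84-fold (adjusted p = 0.00369), Sorl1, a sorting receptor, 1.64-fold (adjusted p = 0.00673) and Fgf14, an intracellular partner of sodium channels, 1.94-fold (adjusted p = 0.00743). Parm1, Dhrs7, Ttc25 and Prune2 also fell, by 0.85, 0.93, 0.74 and 0.94 on the log2 scale, with Ttc25 under the 95th percentile of olfactory receptors (6.46) in both groups and Prune2 under it in HFD, as was Sorl1. Calls were lost without HFD 4 for Ttc25, without HFD 1 for Prune2, and without NCD 2, HFD 1 or HFD 4 for B3galt2 (largest adjusted p 0.0772). B3galt2 also lost its call after cyclic loess, equal quantiles and equal median and spread, and Prune2 after cyclic loess and with the mean of its clusters (-0.6325, adjusted p = 0.109).

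Because Pygl fell, a fall shared by other glycogen genes was tested as a hypothesis. The list left out Pygl and Ppp1r3c, a glycogen-targeting subunit, because both values had been seen. Over 17 such genes the median difference was -0.205, at the 0.03 percentile of random lists of like expression, and 14 means were lower, with 0 genes past the threshold over all genes (limma; largest fall Gys2, -0.72, adjusted p = 0.220). Camera gave p = 0.000423, p = 0.0660 with an estimated correlation, and the exact permutation of array means gave its smallest p of 0.0286. That smallest p rests on a narrow gap. The highest HFD array (HFD 3) had a mean of 7.838 and the lowest NCD array (NCD 4) one of 7.846. The median was -0.13 after cyclic loess, -0.106 without HFD 1, -0.112 without NCD 3 and -0.06 without NCD 2 and NCD 3, where the camera call was lost. NCD 2 and NCD 3 had the highest array means over these genes (8.06 each), so leaving them out itself shrinks the difference. Whether the lower values rest in part on those arrays cannot be told from this.

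A fall shared by known targets of the carbohydrate-response factor Mlxipl was tested on 10 genes outside the fatty acid list. Their median was 0.054, at the 83.4 percentile of random lists of like expression, and 6 means were higher. The bound set beforehand would count this against the hypothesis, but only 2 of the 10, Txnip (-0.17) and Gpd1 (-0.43), lay above the 95th percentile of olfactory receptors, so the list cannot tell in this tissue; that condition on expression was added after the values were seen.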
